A study of Mus musculus with 2 samples.

How the data were processed

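Droplet single-cell RNA sequencing was analysed for 2 libraries of the single group that the labels give: live CD45+ CD11b+ cells (CD45 marks leukocytes, CD11b most myeloid cells) sorted from the pleural fluid of mice with a malignant pleural effusion. Per the labels' protocols, the mice had received 150000 LLC cells, a mouse Lewis lung carcinoma line, in 100 µl into the pleural cavity, the fluid was taken after 10 days, red cells were lysed, and the sorted cells were encapsulated with a 10x Genomics 3' end kit. The authors deposited, for each library, UMI counts (molecules counted per gene and cell barcode), unscaled and already limited to barcodes called as cells. Cell Ranger 3.0.1 and the genome build mm10 are named in the submitters' processing notes; the file headers name that version for library 2 and no software for library 1. The annotation release and whether the counting used strand are not given in the sources used here. Both libraries list 27998 genes; library 2 also holds counts of 2 antibody tags against CD45, named BC2 and BC3, which the labels do not explain. Acod1 is listed under its older symbol Irg1, and immunoglobulin and T cell receptor constant genes of the marker lists were not analysed here.

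Cells with under 300 genes or over 10% mitochondrial UMIs were left out (25 of 1141 barcodes in library 1, 61 of 2908 in library 2). A search for droplets with 2 cell types, which compared each cell's 10 nearest neighbours among cells and simulated pairs, removed 10 and 68 more, at an expected rate in proportion to the number of cells. Counts were scaled to 10000 per cell and logged; 2000 variable genes gave 30 principal components, which were aligned between libraries with a Harmony procedure written in numpy 2.4.6 (penalty 2, 10 rounds). Cells were clustered with leidenalg 0.10.2 on a shared-neighbour graph (15 neighbours, resolution 1, best of 20 starts). A cluster was named when its top 100 genes held at least 3 markers of a class and no other class led its top 10; a cluster that failed either condition stayed unnamed. The 247 genes of the 15 tested lists were kept out of the clustering features and out of the naming. Other genes of the same functions could still serve as features and markers, so a list may differ through how the clusters were drawn.

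UMIs were summed per library and class or cluster with at least 20 cells in each library, and tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr) in R 4.3.3, with the library as a block, since each class is drawn from the same 2 libraries. The block does not cover the 2 antibody tags of library 2, which split by class: 1572 of 1587 neutrophil-like cells lay on the BC3 side and 184 of 197 macrophage-like cells on the BC2 side. Adjusted p-values are Benjamini-Hochberg over all genes tested, and separately over the list members alone; calls are at 0.05. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and with an estimated one, and with fry. With an estimated correlation, camera also relies on the few residual degrees of freedom that 2 libraries leave. A list that fails in that form may fail for want of power, so it cannot tell correlated genes from too few libraries. A log2 fold change is given with a standard error, its absolute value divided by the root of edgeR's moderated F, with n = 2 libraries. It is not the spread of 2 library values. A class with no UMI of a gene was set to a floor of 3 counts over the group. That floor takes the other class's count as exact, while the 95% counting limit beside it does not. The labels do not say that the libraries came from separate animals. Of cells with either, 762 of 762 in library 1 held Y-linked RNA, of male cells, without Xist, of female cells. In library 2, 915 of 1020 on the BC2 side and 334 of 392 on the BC3 side held Xist alone. Y-linked RNA alone was in 47 and 55 cells and both kinds in 58 and 3, in that order. The libraries thus do not share all their animals, and library and sex largely coincide. With the block, p-values measure how far class differences vary between these 2 libraries, pooled over the fitted classes and moderated across genes. That spread comes from an unknown number of animals and may be technical. Levels are in CPM, the gene's UMIs over all gene UMIs of the class in that library, scaled as counts per 1e6. Shares of cells carry exact (Clopper-Pearson) 95% intervals and levels exact Poisson intervals; intervals and floors cover counting error only. Log2 ratios of single libraries are of CPM, with 0.5 UMIs added, without the TMM factor.

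The lists, the markers, the tests and the rule for the genes named were fixed before the data were examined. The lists are efferocytosis receptors and bridging molecules, engulfment and corpse processing, IL-10 axis, TIMPs and metalloproteinases, vascular and effusion mediators, chemokines, chemoattractant receptors, glycolysis, oxidative phosphorylation, lipid handling, arginine and suppressive mediators, antigen presentation, interferon response, cell cycle and dissociation stress. The rule names, per comparison, up to 8 called members of the efferocytosis, IL-10 and TIMP lists and 2 of each other list, those with the largest change in one direction in both libraries (between macrophage clusters, 2 of every list), and always Axl, Mertk, Il10, Il10ra and Timp1 (in the cluster comparison Il10ra was added). Where the text names further members of a list with few calls, these were chosen after their values were seen.

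The edgeR fit was tested on simulated counts with 200 changed genes, 100 at a 2-fold and 100 at a 4-fold change. Of these, 36 and 90 were called for macrophage against dendritic cells, 28 and 85 against monocytes, 26 and 79 against neutrophils (8335 genes tested in each), and 34 and 74 for cluster 10 against cluster 4 (7409 tested). Unchanged genes gave 10, 14, 9 and 5 calls, in that order. Apart from the changed genes, the simulation gave all classes of a library the same profile. Its counts need not hold where many genes differ between classes, as with the 4913 of 8636 called against neutrophil-like cells.

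Several steps were settled after looking at the cells and before any test of genes: the alignment of the libraries, the doublet search, the naming rule's details and the number of clustering starts. Without alignment most clusters held nearly 1 library only. A doublet search with 30 neighbours and 1 simulated pair per cell, in place of 10 and 0.5, left cluster 10 with under 20 cells in library 2. The choice of search is thus what made the comparison of macrophage clusters possible. The 2 changes, named below by the 30 neighbours, were not made apart. The versions set aside were rerun as alternatives, beside DESeq2 1.42.0, other scaling, no low-count filter, no block, other resolutions, list genes as features, count splitting (clusters from a random 0.5 share of each cell's UMIs, tests on the rest), a stricter cell filter, doublets kept, each library clustered on its own and each library left out. Clusters and tests otherwise use the same cells. Reruns given as without alignment left out the Harmony step but scaled each gene within each library. Since that also brings the libraries together in part, they do not show wholly unaligned data. Python 3.11.15, scipy 1.17.1, scikit-learn 1.9.0 and igraph 0.11.9 were used for the cells.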

Results

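Myeloid cells of the pleural fluid were profiled in 2 libraries of 1 group, mice bearing a malignant pleural effusion; no untreated or tumour-free sample is part of the group. Library 1 held 1141 cell barcodes with 11543829 UMIs (median 9894 per barcode) and library 2 held 2908 with 20322996 gene UMIs (median 1954). After filtering, 1106 and 2779 cells formed 15 clusters. With 1 group, the comparisons lie between the cell classes of the effusion. The series title names efferocytosis, the uptake of dying cells, and TIMP1, a secreted inhibitor of metalloproteinases; the question put to each comparison was which classes carried the genes of these and related functions.

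Macrophage-like, monocyte-like, dendritic-like and neutrophil-like cells were found in both libraries, in very different shares. Neutrophil-like cells (S100a8, S100a9, Retnlg, Cxcr2) made up 6.69% (74 of 1106, interval 5.29% to 8.33%) of library 1 and 57.1% (1587 of 2779, interval 55.2% to 59%) of library 2. The smallest deposited barcode held 1999 UMIs in library 1 and 500 in library 2. Neutrophil-like cells of library 2 had a median of 1292 UMIs, so most of them lay below any barcode of library 1. The shares of all classes thus also reflect where barcodes were cut, which the intervals do not cover. Macrophage-like cells made up 26.1% (289 of 1106, interval 23.6% to 28.8%) and 7.09% (197 of 2779, interval 6.16% to 8.11%). They consisted of cluster 4 (C1qa, C1qb, C1qc, Cd163, Folr2) with 263 and 177 cells and cluster 10 (Alox15, Prg4, Saa3, markers of large resident pleural macrophages) with 26 and 20 cells. Dendritic-like cells (Klrd1, H2-DMb2, Cd209a, Mgl2 in cluster 7; Ccr7 and Fscn1 in cluster 15) made up 13.5% (149 of 1106, interval 11.5% to 15.6%) and 3.31% (92 of 2779, interval 2.68% to 4.04%), and monocyte-like cells of cluster 6 (Ly6c2) 10.4% (115 of 1106, interval 8.66% to 12.3%) and 4.82% (134 of 2779, interval 4.06% to 5.69%).

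B-like cells (Cd79a, Cd79b, Ms4a1) took 2.44% (27 of 1106, interval 1.61% to 3.53%) of library 1 and 0.576% (16 of 2779, interval 0.329% to 0.933%) of library 2. Cluster 12, with 11 and 28 cells, met the T cell rule on 3 markers, but its first genes were those of DNA replication (Stmn1, Tk1, Dut), and it is given by number. Cd3 RNA was in 0 and 19 of these cells, and C1q UMIs per cell were 161 and 75.7. Unnamed clusters held 39.9% (441 of 1106, interval 37% to 42.8%) and 26.1% (725 of 2779, interval 24.5% to 27.8%) of the cells. Most of these belonged to clusters 2 and 5, with 37.6% and 22.1%, which carried macrophage markers among their first 100 genes but monocyte genes (Chil3, Vcan and F13a1 in cluster 2; Plac8 and Ms4a4c in cluster 5) in the lead. Mean shares over the libraries were 31.9% ± 35.6 (SD, n = 2) for neutrophil-like, 16.6% ± 13.5 for macrophage-like, 8.39% ± 7.19 for dendritic-like, 7.61% ± 3.94 for monocyte-like and 33% ± 9.75 for unnamed cells. The border between monocyte-like, macrophage-like and unnamed cells moved with the clustering: at resolution 0.5 macrophage-like cells made up 33.5%, monocyte-like cells 20.8% and unnamed cells 2.93%. With library 2 limited to the BC2 side of its antibody tags, the mean of neutrophil-like cells fell to 4.03%.

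**Figure D1:**
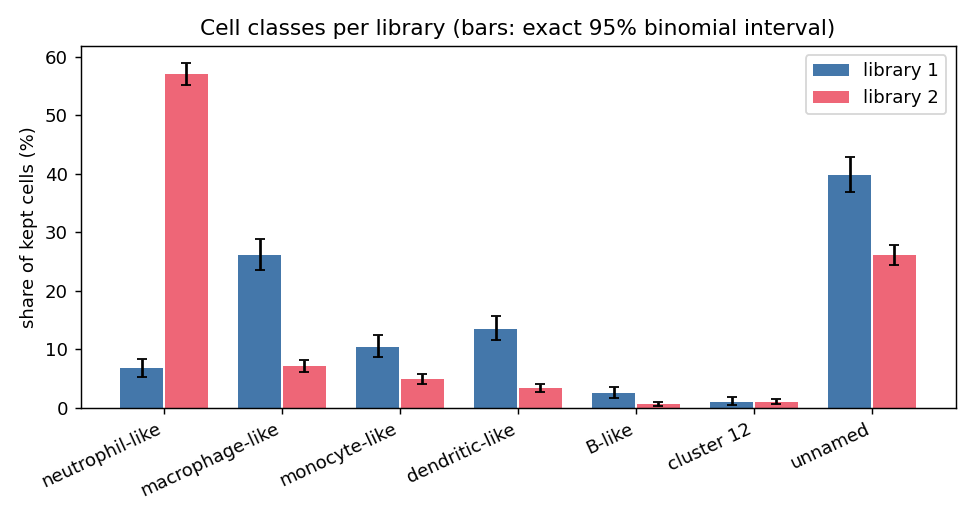
Share of kept cells (%) in each class, for library 1 and library 2, with exact 95% binomial intervals. Neutrophil-like cells took 6.69% of library 1 and 57.1% of library 2, macrophage-like cells 26.1% and 7.09%. The smallest deposited barcode held 1999 UMIs in library 1 and 500 in library 2.

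Markers of other cell types were present at different levels. Genes of tumour or epithelial cells (keratins, Epcam) summed to 3.71 and 1.62 CPM in libraries 1 and 2, those of mesothelial or stromal cells to 1.24 and 0.261, those of endothelial cells to 0.794 and 1.88 and those of mast cells or basophils to 3.44 and 2.87. Erythroid genes reached 76.7 and 5.85. Platelet genes reached 1646 and 186; Ppbp, a platelet chemokine, was also among the first 10 genes of macrophage-like cluster 4. Eosinophil genes gave 134 and 106, plasmacytoid dendritic cell genes 138 and 238, natural killer genes 45.6 and 135, B cell genes 117 and 54.8 and T cell genes 7.77 and 172, without a cluster named for any of the first 3.

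Timp1 was carried by dendritic-like, monocyte-like and macrophage-like cells and was low in neutrophil-like cells and in resident macrophage cluster 10. Its level was 217 ± 98.7 CPM (mean ± SD, n = 2 libraries) in dendritic-like, 102 ± 34.1 in cluster 4, 87.9 ± 36.8 in monocyte-like, 7.97 ± 5.11 in neutrophil-like cells and 7.68 ± 0.225 in cluster 10. Cluster 10 held only 2 and 3 Timp1 UMIs in libraries 1 and 2 (intervals 0.949 to 28.3 and 1.55 to 22 CPM). Its SD thus understates the counting error. Neutrophil-like cells held 2 and 10. Mertk, a receptor tyrosine kinase for dying cells, had its highest level in cluster 10, 57.9 ± 20.9, against 27.7 ± 1.45 in cluster 4, 8.78 ± 11.6 in dendritic-like, 3.57 ± 5.05 in monocyte-like and 0.218 ± 0.308 in neutrophil-like cells. Il10ra, the ligand-binding chain of the interleukin 10 receptor, was at 56.5 ± 18.1 in dendritic-like, 54.4 ± 12.8 in monocyte-like, 21.3 ± 8.09 in cluster 4 and 5.01 ± 7.09 in cluster 10. Il10, an anti-inflammatory cytokine, and Axl, a relative of Mertk, gave few UMIs: Il10 was at 3.8 ± 4.96 and Axl at 4.5 ± 3.46 in macrophage-like cells. The large unnamed clusters 2 and 5 carried these genes too. They held Timp1 at 102 ± 51.6 and 104 ± 62 and Mertk at 24.1 ± 1.63 and 25.5 ± 4.02, near cluster 4. Il10ra stood there at 32.5 ± 17.8 and 31.4 ± 20.4, Il10 at 6.64 ± 8.96 and 7.11 ± 6.06, and Axl at 1.43 ± 0.734 and 3.18 ± 1.82.

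**Figure D2:**
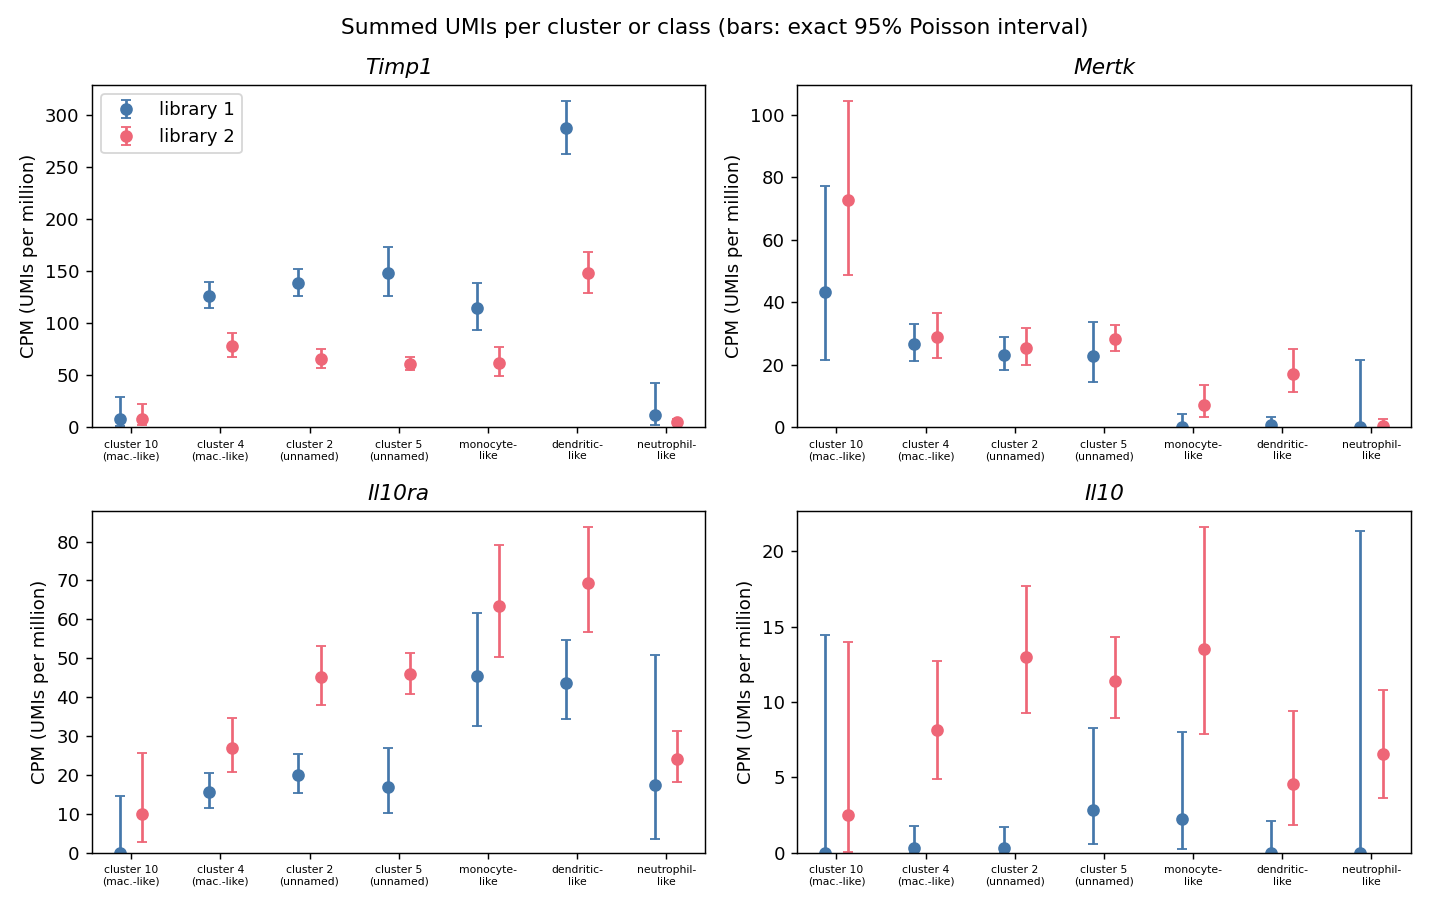
CPM (y axis, 1 panel per gene) of Timp1, Mertk, Il10ra and Il10 in clusters and classes (x axis), for library 1 and library 2, with exact 95% Poisson intervals. Timp1 in dendritic-like cells stood at 287 and 148, in cluster 10 at 7.84 and 7.52, the latter from 2 and 3 UMIs.

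In the GENCODE annotation of the mm10 assembly all 5 are protein-coding genes. Timp1 (ENSMUSG00000001131) lies on chromosome X from 20870166 to 20874735 on the plus strand, inside Syn1 on the minus strand; Syn1 had 73 UMIs over all barcodes and Timp1 3045. Mertk (ENSMUSG00000014361) lies on chromosome 2 from 128698956 to 128802894, plus strand, over the antisense gene Gm14011, which had 0 UMIs. Il10ra (ENSMUSG00000032089) lies on chromosome 9 from 45253837 to 45269149, minus strand, and holds the pseudogene Gm20612, which was not analysed here. Il10 (ENSMUSG00000016529) lies on chromosome 1 from 131019845 to 131024974, plus strand, and Axl (ENSMUSG00000002602) on chromosome 7 from 25757273 to 25788705, minus strand, neither with an overlapping gene.

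Compared with dendritic-like cells, macrophage-like cells carried less Timp1, Il10ra and Ciita RNA and more RNA of 4 of 21 engulfment and corpse processing genes. Timp1 was lower in macrophage-like cells (log2 fold change -1.32 ± 0.24, edgeR adjusted p = 0.00124, n = 2 libraries), while Timp2, another inhibitor of metalloproteinases, was higher (3.46 ± 0.66, edgeR adjusted p = 0.019). Ciita, the master regulator of MHC class II transcription, was lower by far (-4.86 ± 0.58), as were Cd86 (-0.90 ± 0.26), a costimulatory ligand, and the dendritic cell chemokines Ccl22, at least 37.3-fold (95% counting limit 29.4) lower, and Ccl5 (-6.84 ± 0.88). Lipoprotein lipase Lpl (3.23 ± 0.38), the fatty acid carrier Fabp4 (3.08 ± 0.39), the cholesterol exporter Abca1 (2.84 ± 0.50) and the lysosomal protease Ctsd (1.91 ± 0.32) were higher. Of macrophage-like Fabp4 UMIs, 232 of 249 lay in cluster 10, which held 26 and 20 of the macrophage-like cells. Cluster 10 also held 2870 of 10213 macrophage-like Ctsd and 177 of 688 Timp2 UMIs, but 3 of 586 of Lpl and 8 of 184 of Abca1.

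Among efferocytosis receptors and bridging molecules, 3 of 16 members higher and 2 lower passed the test. Itgb5 (1.95 ± 0.38), Pros1 (1.10 ± 0.33), the bridging protein S, and Cd300lb (0.99 ± 0.31) were higher; Timd4 (-2.89 ± 0.40), a phosphatidylserine receptor, and Mfge8 (-2.13 ± 0.52), a bridging molecule, were lower. Cluster 10 held 74 of 211 macrophage-like Pros1 UMIs, against 12 of 209 of Itgb5 and 23 of 270 of Cd300lb. Mertk did not pass (2.03 ± 0.68, edgeR adjusted p = 0.105). It passed in 5 of 18 alternatives with a test, among them leaving out dendritic-like cells with over 5 C1q UMIs (4.78, adjusted p = 1.25e-06; adjusted p = 1.25e-06 to 0.459 over all). Axl (-0.72 ± 0.58, edgeR adjusted p = 0.512) and Il10 (0.68 ± 0.72, edgeR adjusted p = 0.641) did not pass either. On the IL-10 axis 3 of 15 members were lower: the repressor Etv3 (-2.43 ± 0.30), Il10ra (-1.64 ± 0.26, edgeR adjusted p = 0.000296) and the kinase Tyk2 (-1.57 ± 0.39). Timp1 and Timp2 were the called members among 12 TIMPs and metalloproteinases. Without the library block the Timp1 call was lost (adjusted p = 0.215).

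Interferon response genes were lower in 5 of 9 members (Ifit2 -2.48 ± 0.52, Isg15 -1.97 ± 0.41, also Oasl2 and Usp18). Antigen presentation genes were lower in 2 of 10 (10 at an unadjusted p under 0.05, 8 lower with DESeq2). Dendritic-like cluster 7 was itself led by the related genes H2-DMb2 and H2-Oa. The antigen presentation difference may thus follow in part from how that class was drawn and named. Engulfment and corpse processing had 4 of 21 members higher and 0 lower (also Ctsb and Lamp1), vascular and effusion mediators 3 of 9 members higher and 1 lower: Il1b, a fever cytokine, was lower (-2.87 ± 0.29) and the ribonuclease Ang higher (2.31 ± 0.60), with Nrp1 and Plaur. Chemokines split into 3 higher (Ccl8, Ccl9, Cxcl3) and 3 lower (also Cxcl16), and lipid handling into 3 and 3. The checkpoint ligand Pdcd1lg2 was at least 34.2-fold (95% counting limit 26.9) lower and Nt5e, which makes adenosine, higher by a ratio of 12.6 (95% counting interval 3.3 to 107), with 44 of 47 macrophage-like UMIs in cluster 10. The cell cycle genes Birc5 (3.07 ± 0.63) and Ccnb2 (2.88 ± 0.56) were higher, with 65 of 70 and 101 of 105 macrophage-like UMIs in cluster 10. The glycolytic enzyme Pfkp was lower (-1.94 ± 0.28). For oxidative phosphorylation, chemoattractant receptors and dissociation stress edgeR called 0 members, with 0 of 20, 2 of 10 and 1 of 13 at an unadjusted p under 0.05; DESeq2 called 0, 1 and 0.

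Over all genes, 1120 of 8636 passed, 450 higher and 670 lower in macrophage-like cells, from 3409238 and 2734394 summed UMIs against 1761625 and 1530758. Of 205 list genes, 43 passed (21 higher, 22 lower), and 51 when adjusted over the list alone. As sets, antigen presentation (camera adjusted p = 1.36e-08, and adjusted p = 0.365 with an estimated correlation) and interferon response (adjusted p = 2.13e-05, and adjusted p = 0.365 with an estimated correlation) were lower against other genes. Chemokines (adjusted p = 0.00165, and adjusted p = 0.365 with an estimated correlation), efferocytosis (adjusted p = 0.0147, and adjusted p = 0.365 with an estimated correlation), engulfment (adjusted p = 0.0161, and adjusted p = 0.614 with an estimated correlation), TIMPs and metalloproteinases (adjusted p = 0.0309, and adjusted p = 0.365 with an estimated correlation), vascular mediators (adjusted p = 0.0341, and adjusted p = 0.365 with an estimated correlation) and glycolysis (adjusted p = 0.0341, and adjusted p = 0.614 with an estimated correlation) were higher, glycolysis although Pfkp, its 1 called member, was lower. With fry 0 of 15 lists passed (smallest adjusted p = 0.246; 3 at an unadjusted p under 0.05). Dendritic-like cells of library 2 held C1qa, a macrophage gene, at 421 CPM, those of library 1 at 42.6, and 28 of the 43 called list genes had ratios over 1.5 times apart between libraries, and in all 28 the larger was that of library 1 (Mfge8 -2.82 and -0.78, Timp2 5.33 and 2.52, Ifit2 -5.20 and -2.09). The count of 43 was 16 without the library block and 90 without cells of over 5 C1q UMIs.

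Against monocyte-like cells, macrophage-like cells carried more RNA of 6 engulfment and corpse processing genes and less of 4 IL-10 axis and 4 glycolysis genes; Timp1 showed no detectable difference. Timp1 had a log2 fold change of 0.01 ± 0.25, edgeR adjusted p = 0.997 (n = 2 libraries). Fabp4 was higher by a ratio of 43.9 (95% counting interval 12 to 364), with 232 of 249 macrophage-like UMIs in cluster 10, and Lpl by 3.96 ± 0.46 on the log2 scale; the lysosomal lipase Lipa (1.90 ± 0.33, edgeR adjusted p = 0.00158) and Abca1 (2.15 ± 0.51) were higher too. Il1b (-3.09 ± 0.29, edgeR adjusted p = 3.19e-06), the glucose transporter Slc2a1 (-1.63 ± 0.27) and Pfkp (-1.73 ± 0.28) were lower. Il10ra was lower (-1.58 ± 0.27, edgeR adjusted p = 0.00134).

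Of engulfment and corpse processing genes, 6 of 21 members higher and 0 lower passed. Of efferocytosis receptors the single called member was Timd4, with 1 UMI in library 1 and 48 in library 2 against 0 and 0 in monocyte-like cells, so that its call rests on library 2. Mertk (3.07 ± 0.86, edgeR adjusted p = 0.0803) and Axl (ratio 9.16 (95% counting interval 1.5 to 375), edgeR adjusted p = 0.135) did not pass, nor did Il10 (-1.17 ± 0.61, edgeR adjusted p = 0.273). Adjusted over the list alone Mertk passed (adjusted p = 0.0325), and it passed over all genes in 5 of 18 alternatives (log2 fold change 2.58 to 4.01; adjusted p = 1.06e-07 to 0.729 over all alternatives). IL-10 axis members were lower in 4 of 15: besides Il10ra the receptor antagonist Il1rn (-2.74 ± 0.43), Bcl3 (-1.18 ± 0.30) and Nfil3 (-1.10 ± 0.29). Of TIMPs and metalloproteinases, Timp2 (3.89 ± 0.74) and the integrin Itgb1 (1.12 ± 0.26) were higher, and the collagenase Mmp8 (-4.67 ± 0.68), Mmp19 (-1.69 ± 0.27) and Adam8 (-1.43 ± 0.34) lower, among 12 tested. Cluster 10 held 177 of 688 macrophage-like Timp2 UMIs and 549 of 1516 of Itgb1.

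Glycolysis had 4 of 17 members lower (also Hk2 and Slc16a3). Lipid handling split into 2 higher, Lpl and Fabp4, and 4 lower, among them Hmgcs1 and Sqle of sterol synthesis. Vascular mediators had 1 of 9 members higher and 4 lower, the semaphorin and VEGF co-receptor Nrp1 (3.05 ± 0.41) against Il1b, Vegfa, Osm and Hif1a. The chemokines Ccl8 (4.10 ± 0.46) and Cxcl16 (1.34 ± 0.32) were higher and the receptors Cx3cr1 (-2.18 ± 0.56) and Ccr1 (-0.95 ± 0.27) lower. Cd80 was lower (-2.0 ± 0.37), as was Cd86, and Cd40 higher (1.32 ± 0.39); these are costimulatory molecules. Of suppressive mediators, Nos2, which makes nitric oxide, was at least 5.68-fold (95% counting limit 3.34) and Pdcd1lg2 at least 4.73-fold (95% counting limit 2.6) lower, while Odc1 was higher. The interferon gene Oasl2 was lower (-1.19 ± 0.33). The cell cycle genes Birc5, at least 8.22-fold (95% counting limit 6.51), and Ccnb2, by a ratio of 18.5 (95% counting interval 4.99 to 155), were higher, with 65 of 70 and 101 of 105 macrophage-like UMIs in cluster 10. Mcm3, with 6 of 83 there, was higher too.

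In all, 648 of 8636 genes passed edgeR's test, 338 higher and 310 lower, against 903988 and 1259865 summed UMIs of monocyte-like cells. Of the list genes 45 passed (19 higher, 26 lower; 44 with 1 direction in both libraries), and 59 when adjusted over the list alone. Cell cycle (camera adjusted p = 0.00168, and adjusted p = 0.588 with an estimated correlation), engulfment (adjusted p = 0.0196, and adjusted p = 0.588 with an estimated correlation) and chemokines (adjusted p = 0.0286, and adjusted p = 0.588 with an estimated correlation) were higher as sets, and the IL-10 axis (adjusted p = 0.00168, and adjusted p = 0.588 with an estimated correlation), chemoattractant receptors (adjusted p = 0.0286, and adjusted p = 0.588 with an estimated correlation) and interferon response (adjusted p = 0.0286, and adjusted p = 0.588 with an estimated correlation) lower. With fry 0 of 15 lists passed (smallest adjusted p = 0.231; 2 at an unadjusted p under 0.05). The count of 45 fell to 5 with the stricter cell filter and to 5 without alignment. It fell to 11 without the library block and to 10 at resolution 0.5, where monocyte-like cells take in part of the unnamed clusters. The Il10ra call was lost in both and in all in 8 of 18 alternatives with a test, with log2 fold changes of -1.58 to -0.52 in these (adjusted p = 3.29e-05 to 0.467 over all alternatives). Ratios were over 1.5 times apart between libraries for 17 of the called list genes.

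**Figure D3:**
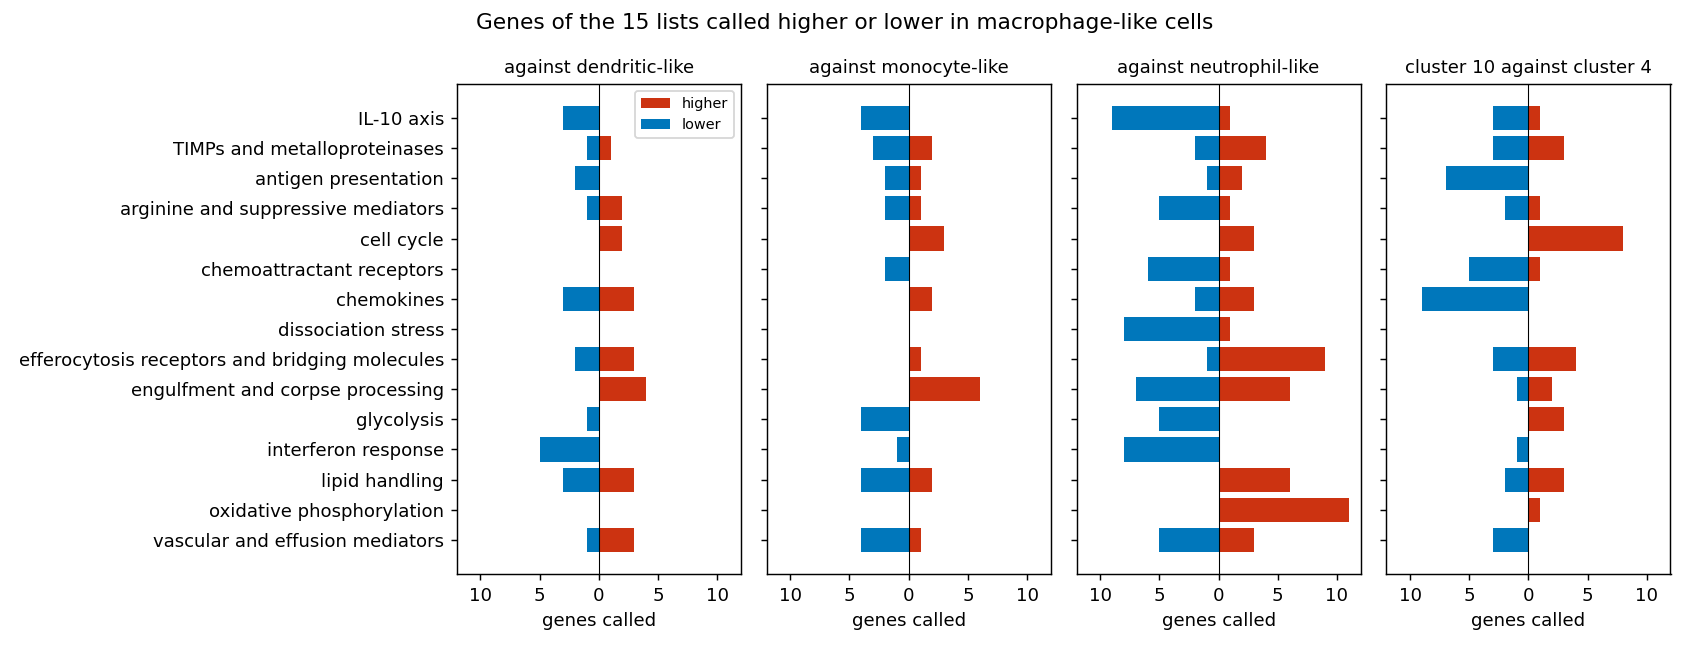
Number of genes (x axis) of each of the 15 lists (y axis) called higher (red, to the right) or lower (blue, to the left) in macrophage-like cells against dendritic-like, monocyte-like and neutrophil-like cells, and in cluster 10 against cluster 4. Oxidative phosphorylation has 11 genes higher against neutrophil-like cells and 0 against dendritic-like cells.

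Against neutrophil-like cells, macrophage-like cells carried more Timp1 and more RNA of 9 of 16 efferocytosis and 11 of 20 oxidative phosphorylation genes. They carried less of 8 of 9 interferon response, 8 of 13 dissociation stress and 9 of 15 IL-10 axis genes; as sets, the smallest camera result was adjusted p = 0.552 with an estimated correlation. Timp1 was higher (3.10 ± 0.39, edgeR adjusted p = 3.69e-06, n = 2 libraries). Mertk had 191 UMIs in macrophage-like and 1 in neutrophil-like cells, a ratio of 76.7 (95% counting interval 13.6 to 3046) (edgeR adjusted p = 0.00866). Lrp1 (4.54 ± 0.92, edgeR adjusted p = 0.00822), a scavenger and lipoprotein receptor, was higher, and so was Uqcrb of respiratory complex III (2.32 ± 0.29, edgeR adjusted p = 3.38e-06). Il1b (-6.78 ± 0.34, edgeR adjusted p = 1.15e-10), Il1rn (-5.64 ± 0.43) and Mmp9 (-5.24 ± 0.70), a gelatinase stored in neutrophil granules, were lower. In library 2 this comparison is also one between tag sides, with 1572 of 1587 neutrophil-like cells on the BC3 side and 184 of 197 macrophage-like cells on the BC2 side. The test cannot part the 2 there, and the BC2 side alone held too few neutrophil-like cells (15) for it.

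Of efferocytosis genes, 9 of 16 members higher and 1 lower passed. Higher were also Pros1 (3.85 ± 0.58), Scarb1 (3.30 ± 0.48), Stab1 (3.0 ± 0.85), Itgb5 (2.70 ± 0.57) and Scarf1 (ratio 13.5 (95% counting interval 3.58 to 113)), and lower the inhibitory receptor Cd300lf (-4.06 ± 0.28). Axl, at least 3.48-fold (95% counting limit 2.64) higher over both libraries (edgeR adjusted p = 0.0152), had 7 UMIs in library 1 against 0 in a class of 172711 UMIs, too few for a direction in that library. Its call was lost with DESeq2 (adjusted p = 0.0693). The Mertk call was lost without the library block and without alignment (adjusted p = 0.0565 and 0.0808; 1.42e-11 to 0.0808 over all alternatives). On the IL-10 axis 9 of 15 members were lower, among them Socs3 (-3.32 ± 0.34), a feedback inhibitor of cytokine signalling, Nfil3 (-2.83 ± 0.31), Sbno2 (-2.51 ± 0.45), Jak1 (-1.84 ± 0.26), Stat3 (-1.58 ± 0.27) and Bcl3 (-1.34 ± 0.33), and Tgfb1 was higher (1.75 ± 0.29). Il10ra (-0.77 ± 0.33, edgeR adjusted p = 0.0542) and Il10 (-0.63 ± 0.64, edgeR adjusted p = 0.418) did not pass. Of 12 TIMPs and metalloproteinases, Itgb1 (1.69 ± 0.30), Adam9 (0.97 ± 0.32) and Mmp14 (ratio 37.8 (95% counting interval 6.61 to 1507)) were higher with Timp1, and Mmp8 (-6.58 ± 0.73) lower with Mmp9. Cluster 10 held 549 of 1516 macrophage-like Itgb1 UMIs, 31 of 377 of Adam9 and 1 of 94 of Mmp14. It also held 74 of 211 of the Pros1 UMIs.

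Oxidative phosphorylation had 11 of 20 members higher and 0 lower, Cyc1 (1.94 ± 0.31) after Uqcrb, while glycolysis had 0 higher and 5 of 17 lower, Slc2a1 (-2.58 ± 0.28) and Hk1 (-1.68 ± 0.29) first. Lipid handling had 6 of 17 members higher and 0 lower, led by Lpl, at least 78.5-fold (95% counting limit 63.6) higher, and Fabp4 (4.25 ± 0.54; 232 of 249 macrophage-like UMIs in cluster 10). Interferon response genes were lower in 8 of 9 (Rsad2 -4.66 ± 0.46, Ifit1 -3.95 ± 0.92) and dissociation stress genes in 8 of 13 (Egr1 -5.38 ± 0.35, Junb -3.26 ± 0.28). Among chemoattractant receptors 6 of 10 were lower, with Cxcr4 (-4.44 ± 0.42) and Ccrl2 (-4.38 ± 0.40) lowest; among chemokines Ccl8 (5.28 ± 0.56) and Ccl9 (3.98 ± 0.33) were highest. Engulfment genes went both ways, 6 higher, such as the lysosomal protease Ctsl (3.24 ± 0.89) and Dock1 (ratio 14.5 (95% counting interval 2.44 to 587)), and 7 lower. The list's median (-0.17) and mean (0.38) differed in sign. Vascular mediators had 3 of 9 members higher and 5 lower, with Nrp1 (5.75 ± 0.62) highest. Nos2 was at least 31.5-fold (95% counting limit 24.4) and Pdcd1lg2 at least 3.32-fold (95% counting limit 1.64) lower. Cd40 was higher (ratio 20.8 (95% counting interval 6.97 to 102)) and Cd80 lower (-1.43 ± 0.48). Mcm3, a replication helicase, was at least 11.1-fold (95% counting limit 8.84) and Ccnb2 1.87 ± 0.63 on the log2 scale higher, with 6 of 83 and 101 of 105 macrophage-like UMIs in cluster 10.

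The test called 4913 of 8636 genes, 2584 higher and 2329 lower, and 110 list genes (51 higher, 59 lower; 105 with 1 direction in both libraries), or 109 when adjusted over the list alone. Interferon response (camera adjusted p = 0.000755, and adjusted p = 0.552 with an estimated correlation), dissociation stress (adjusted p = 0.00156, and adjusted p = 0.552 with an estimated correlation), IL-10 axis (adjusted p = 0.0133, and adjusted p = 0.552 with an estimated correlation) and glycolysis (adjusted p = 0.0351, and adjusted p = 0.568 with an estimated correlation) were lower as sets and efferocytosis (adjusted p = 0.0225, and adjusted p = 0.552 with an estimated correlation) higher. Fry passed 10 of 15 lists (smallest adjusted p = 0.0217), oxidative phosphorylation (adjusted p = 0.0257) among those higher; with camera that list did not pass (adjusted p = 0.059, and adjusted p = 0.65 with an estimated correlation). Neutrophil-like cells held a median of 2166 and 1292 UMIs per cell, macrophage-like cells 11716 and 12552, and the median log2 fold change of all genes was 0.15 with TMM and 0.39 with DESeq2's size factors, relative to which the changes are to be read. With DESeq2's size factors edgeR called 5204 genes, 3127 higher and 2077 lower, so the balance of higher and lower calls depends on the scaling. The smallest barcode of library 1 held 1999 UMIs, so its neutrophil-like cells were only those of higher depth. Between libraries the ratios of 55 of the called list genes were over 1.5 times apart; Plaur, Nr1h2 and Il10rb were called with opposite signs in the libraries. For Timd4 and Axl, with 1 and 7 UMIs against 0 in library 1, the sign there is set by the 0.5 UMIs added.

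Within the macrophage-like cells, resident cluster 10 carried more RNA of 8 of 10 cell cycle genes and less Timp1 and less of 9 of 13 chemokine and 7 of 8 antigen presentation genes than cluster 4. As sets, the smallest camera result was adjusted p = 0.895 with an estimated correlation. That form could hardly pass here, since 2 clusters in 2 libraries with a block leave 1 residual degree of freedom. The residuals of any 2 genes then correlate fully, with a plus or a minus sign. The estimates thus only reflect how these signs split within a list and cannot measure correlation between its genes. They were -0.067 for cell cycle, -0.143 for antigen presentation, 0.436 for chemokines and 0.5 for chemoattractant receptors. Timp1 was lower in cluster 10 (-3.65 ± 0.41, edgeR adjusted p = 1.93e-05, n = 2 libraries) and Mertk higher (1.09 ± 0.33, edgeR adjusted p = 0.0395). Timp1 rests there on 2 and 3 UMIs, against 398 and 182 in cluster 4. Ccnb2, a mitotic cyclin, was higher (7.65 ± 0.42, edgeR adjusted p = 1.5e-08), and the ubiquitin-conjugating enzyme Ube2c by a ratio of 218 (95% counting interval 35.9 to 8948). The cell cycle genes compare the clusters as drawn, with cycling cells of cluster 12 in neither. The list summed to 584 and 504 CPM in cluster 10 (libraries 1 and 2) and 118 and 92.5 in cluster 4. With the 11 and 9 cells of cluster 12 without Cd3 RNA, which held 161 and 82.9 C1q UMIs each, cluster 4 came to 295 and 270.2. Cd74, the invariant chain of MHC class II (-2.53 ± 0.19, edgeR adjusted p = 4.3e-07), and the neutrophil-attracting chemokine Cxcl3 (-4.26 ± 0.37, edgeR adjusted p = 1.84e-06) were lower, and Ccl8 was lower by a ratio of 112 (95% counting interval 20.1 to 4432).

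Cell cycle genes had 8 of 10 members higher and 0 lower, chemokines 0 of 13 members higher and 9 lower and antigen presentation 0 of 8 members higher and 7 lower, Cd40 among them (-2.32 ± 0.61). Chemoattractant receptors had 1 of 8 members higher and 5 lower (Ltb4r1 -2.48 ± 0.23). Efferocytosis genes had 4 of 16 members higher and 3 lower: Mfge8 (3.51 ± 0.47) was higher with Mertk, Pros1 and Thbs1, and Cd36 was lower by a ratio of 17.7 (95% counting interval 6.03 to 86.4) with Stab1 and Msr1. Axl went opposite ways, with 3 UMIs in cluster 10 and 4 in cluster 4 in library 1 (11.8 and 1.27 CPM) and 0 and 19 in library 2 (0 and 8.14 CPM). Its ratio over both libraries, 1.09 (95% counting interval 0.21 to 3.62), did not pass (edgeR adjusted p = 0.983). Il10ra did not pass either (-1.88 ± 0.67, edgeR adjusted p = 0.083), and passed in 5 of 13 alternatives (adjusted p = 0.00179 to 0.58 over all). Alternatives that clustered the cells anew set cluster 10 against all their other macrophage-like clusters, which need not match cluster 4. Il10 fell under the low-count filter, with 0 and 1 UMIs in cluster 10 and 1 and 19 in cluster 4. On the IL-10 axis the transcription factor Maf (-3.05 ± 0.26) and Il4ra (-1.81 ± 0.22) were lower with Tgfb1, and Socs3 higher, among 13 tested. Of TIMPs and metalloproteinases 3 of 12 were higher, with the macrophage elastase Mmp12 (5.21 ± 0.63) first, and 3 lower.

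Ctsd (1.80 ± 0.14) and Lamp2 were higher and Ctsb lower (-0.94 ± 0.16) among 18 engulfment genes. The mitochondrial fatty acid enzyme Acadl was higher (2.86 ± 0.19), with Hadhb and Acadm, and Lpl lower by a ratio of 23.1 (95% counting interval 7.88 to 113), with Fabp5. Pfkl (0.92 ± 0.21), Gpi1 (0.70 ± 0.17) and Aldoa were higher of 17 glycolysis genes, Uqcrc2 (0.76 ± 0.20) of 20 oxidative phosphorylation genes. Nt5e was higher by a ratio of 123 (95% counting interval 39.5 to 619.9), Hmox1, which breaks down heme, lower (-1.33 ± 0.16) with Lgals3. Nrp1 (-1.76 ± 0.29), Hif1a (-1.60 ± 0.24) and Il1b were lower of 7 vascular mediators, and Isg15 of 7 interferon genes; dissociation stress had 0 of 13 members higher and 0 lower with edgeR (3 at an unadjusted p under 0.05) and 0 calls with DESeq2.

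Of 7820 genes, 1086 passed, 648 higher and 438 lower in cluster 10. Of 187 list genes, 66 passed (27 higher, 39 lower), and 79 when adjusted over the list alone. Chemokines (camera adjusted p = 5.5e-07, and adjusted p = 0.895 with an estimated correlation), antigen presentation (adjusted p = 0.000116, and adjusted p = 0.895 with an estimated correlation) and chemoattractant receptors (adjusted p = 0.0112, and adjusted p = 0.895 with an estimated correlation) were lower as sets and cell cycle (adjusted p = 2.34e-05, and adjusted p = 0.895 with an estimated correlation) higher. With fry 0 of 15 lists passed (smallest adjusted p = 0.208; 2 at an unadjusted p under 0.05). Cluster 10 rests on 26 and 20 cells; 27 list genes passed without the library block and 43 with DESeq2, both of which ended the Mertk call (adjusted p = 0.14 and 0.619). Ratios were over 1.5 times apart between libraries for 35 of the called list genes.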

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

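All 3 tests of this part were chosen after the result was seen. Antibody tag counts, which the comparisons do not use, made up 44.6% of all counts of library 2, and 60.5% of its kept cells lay on the BC3 side of the tags; the labels mention neither tag, and a tag signal of any size stands above the limit that a count of 0 allows. The tags split by cell class: 1572 of 1587 neutrophil-like cells (99.1%) lay on the BC3 side, against 6.6% of macrophage-like, 14.9% of monocyte-like and 18.5% of dendritic-like cells.

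Neutrophil-like cells had a median BC3 count of 2090 and macrophage-like cells of 702, a ratio of 2.98, which argues against mere background of the tag. If the cell class alone set the tag in 1 stained sample, mononuclear phagocytes on both sides would come from the same animals; of those with Xist or Y-linked RNA, 36.7% on the BC3 side had Y-linked RNA alone (interval 23.4% to 51.7%) against 4.63% on the BC2 side (3.31% to 6.28%). Both tags lay above the midpoints in 3.38% of cells (94 of 2779), so a candidate explanation is that a separately tagged pool or pools supplied the BC3 cells. Neutrophil-like cells on the BC3 side, of lower depth, had Y-linked RNA alone in 10.2% of those with either (6.99% to 14.2%), apart from the phagocytes of that side, so 1 evenly mixed pool for both is not shown. What the pools were stays open, and no biological explanation was tested, because the labels give 1 group.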

How the results depend on the processing

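All alternatives that concern the tags, the UMI and C1q limits, naming, the doublet search with 30 neighbours, the single clustering start and the missing alignment, and count splitting for the shares, were chosen after seeing the data. List genes called both in the results above and under an alternative kept their direction in every comparison and alternative with a test. Called list genes against dendritic-like cells (43) numbered 70 without the low-count filter, 27 on the BC2 side alone, 77 without cells of over 20000 UMIs and 90 without dendritic-like and B-like cells of over 5 C1q UMIs. They numbered 22 with 30 doublet neighbours and 1 simulated pair per cell in place of 0.5, changed together. They numbered 24 without alignment, that is with genes scaled within each library and no Harmony step. Against monocyte-like cells (45) they numbered 10 at resolution 0.5, 12 at resolution 2, 20 with count splitting, 5 with the stricter cell filter and 71 with the C1q limit. They numbered 20 with 30 neighbours and 1 simulated pair per cell, 24 with naming by list genes in the top 50 and 5 without alignment. Against neutrophil-like cells (110) all alternatives gave 94 to 139. Between clusters 10 and 4 (66) DESeq2 gave 43. Reruns that clustered the cells anew set cluster 10 against all their other macrophage-like clusters, which need not match cluster 4. Count splitting gave 34 in that form, with 473 and 522 macrophage-like cells in libraries 1 and 2 against 289 and 197 in the results above. Without the library block the counts were 16 against dendritic-like, 11 against monocyte-like, 94 against neutrophil-like cells and 27 between clusters; the block also decided the calls of Timp1 against dendritic-like, Il10ra against monocyte-like, Mertk against neutrophil-like cells and Mertk between clusters, and no other call of Timp1, Mertk, Axl, Il10 or Il10ra. Il10ra against monocyte-like cells was also lost at resolutions 0.5 and 2, with list genes as features, count splitting, the stricter filter, 30 doublet neighbours and no alignment. Mertk passed without the low-count filter, with doublets kept and with the UMI and C1q limits against dendritic-like and monocyte-like cells, with count splitting against the former and with DESeq2 against the latter, and between clusters it was lost with DESeq2 and with doublets kept. Axl passed against monocyte-like cells with the UMI limit. The cause was not tested.

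Mean shares moved for macrophage-like cells (16.6%) to 33.5% at resolution 0.5, 32% with the stricter filter, 30.8% with count splitting, 29.6% without alignment and 28.4% at resolution 2. They moved to 26.4% with 30 doublet neighbours and 1 simulated pair per cell, and to 25.2% with each library on its own. Neutrophil-like cells (31.9%) moved to 4.03% on the BC2 side alone. Monocyte-like cells (7.61%) moved to 20.8% and 19.8% at resolutions 0.5 and 2, 17.4% with list genes as features, 25% with the stricter filter, 27.6% with naming in the top 50, 25.6% without alignment, 16.3% with each library on its own and 20.3% with count splitting. Unnamed cells (33%) moved, for these in turn, to 2.93%, 11.6%, 13.4%, 2.69%, 13%, 0%, 13.7% and 5.12%, and to 51% on the BC2 side alone. Leaving out a library gave ranges of 7.09% to 26.1% for macrophage-like, 4.82% to 10.4% for monocyte-like, 3.31% to 13.5% for dendritic-like, 6.69% to 57.1% for neutrophil-like and 26.1% to 39.9% for unnamed cells. With 1 library left there is no residual spread and no test; single-library log2 ratios of Timp1 were -1.29 and -1.13 against dendritic-like and -3.69 and -3.15 between clusters, and Axl against neutrophil-like cells ranged from -0.40 without replicate 2, a sign set by the 0.5 UMIs added to a count of 0, to 5.03 without replicate 1. Cluster 10 fell below 20 cells in a library on the BC2 side alone, with the UMI limit, and with 30 doublet neighbours, neutrophil-like cells on the BC2 side alone, and every other macrophage-like cluster without alignment, so these tests could not be run. The cause of these changes was not tested. Depth limits Il10 and Axl, the latter in neutrophil-like cells of library 1, a class of 172711 UMIs, above all.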

Other observations

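The comparison of phagocyte clusters and all tests of this part were chosen after the results were seen, except the test of sex, whose prediction was written before its result. The unnamed clusters 2 and 5, macrophage-like clusters 4 and 10 and monocyte-like cluster 6 held 74.1% of library 1 and 34% of library 2; each was tested against the mean of the other 4, and CPM values below are for libraries 1 and 2, beside those of the other 4 summed. Cluster 2 carried more glycolysis RNA (9 of 17 members higher; camera adjusted p = 2.4e-05, and adjusted p = 0.417 with an estimated correlation; Pgk1 0.75 ± 0.12, Tpi1 0.74 ± 0.10 on the log2 scale, n = 2 libraries), more RNA of chemoattractant receptors (6 of 10; in cluster 6 also 6), and more Nos2, the inducible nitric oxide synthase (6.96 and 6.81 CPM against 0.558 and 1.14). Cluster 5 carried more interferon response RNA (5 of 9, camera adjusted p = 3.61e-06, and adjusted p = 0.335 with an estimated correlation). Ifit3 stood at 5.66 and 59.1 CPM against 0.131 and 24.2, and Rsad2 at 4.72 and 40 CPM against 0.788 and 20.8. The first genes of cluster 5 outside the lists (Ifi27l2a, Zbp1, Rtp4) are interferon-induced too. This result may therefore follow from how the cluster was drawn. Cluster 4 was higher for Ccl8 (36.1 and 354 CPM against 0.724 and 36.3) and Pf4 (2.01 ± 0.16 on the log2 scale), with 7 of 21 engulfment genes higher and 5 glycolysis genes lower.

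Cluster 6 had 9 engulfment genes lower, Mertk lower (-2.89 ± 0.41) and Il10ra higher (1.57 ± 0.24), with Il1b (2.66 ± 0.16) and the sterol synthesis gene Hmgcs1 (2.40 ± 0.21). Dissociation stress genes moved there too, with 6 of 13 higher (camera adjusted p = 0.0171, and adjusted p = 0.441 with an estimated correlation). Of the same 13 genes, 3 were higher in cluster 2, 3 lower in cluster 4 and 5 lower in cluster 10. Cluster 10 had 10 of 14 cell cycle genes higher, with cycling cells of cluster 12 left out (Ccnb2 192 and 130.4 CPM against 0.712 and 0.304), Fabp4 higher (153 and 484 CPM against 2.14 and 0.456) and Timp1 lower (-3.59 ± 0.40). Of 212 list genes tested, 32 were higher and 6 lower in cluster 2, 27 and 23 in cluster 4, 23 and 8 in cluster 5, 47 and 30 in cluster 6 and 38 and 50 in cluster 10 (edgeR, over all genes); in 5 of these calls (Pf4, Maf and Cxcl16 in cluster 2, Ccl8 in cluster 5, Timp1 in cluster 6) the CPM lay on the other side of the summed value in both libraries, since the sum weights clusters by their UMIs. The mean of the other 4 weighs each cluster alike, so low values of small cluster 10 can make the rest appear higher. Timp1 was called higher in clusters 2, 4, 5 and 6 at once and lower in cluster 10. Maf and Cxcl16 were called higher in clusters 2, 4 and 5 and lower in cluster 10. These counts of calls are thus not all traits of 1 cluster. No list of any of these clusters passed camera with an estimated correlation.

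Lymphoid and dendritic-like cells of library 2 (clusters 7, 9, 11 and 15) carried RNA of C1qa, C1qb and C1qc, complement genes of macrophages. On the BC2 side 104 cells held 45.4 such UMIs on average and on the BC3 side 48 cells held 0.229, a ratio of 198; free RNA reaches every droplet, so this argues against it as the main source. On the BC2 side, cells above the median share of C1q among their UMIs had 2.06 times the median UMIs of the others (24979.5 against 12150, bootstrap interval of the ratio 1.67 to 2.45; 1.61 within cluster 7 and 3.05 within cluster 9), as a hypothesis of 2 cells in a droplet, whether joined, paired by chance or 1 inside the other, would need. Chance pairing of both tag pools would give 47.8% of cells with over 5 C1q UMIs, kept or called doublets, both tags if partners came from all cells, fewer if from macrophage-like cells (6.6% on the BC3 side); 17.4% had both (16 of 92, interval 10.3% to 26.7%; 12 of 32 called doublets and 4 of 60 kept cells), which leaves chance pairing and physically joined cells open. RNA of both sexes in 1 droplet was not limited to these clusters. In phagocyte clusters 2, 4, 5, 6 and 10, Xist and Y-linked RNA were together in 44 of 842 cells with either on the BC2 side. On the BC3 side they were together in 0 of 49. The source of these mixed droplets was not tested. No biological explanation was tested, since the design gives 1 group.

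Il10 was higher in library 2 than in library 1 in the phagocyte clusters 2, 4, 5, 6 and 10, with 151 UMIs against 7, a ratio per UMI of 13.8 (6.53 to 34.9). A different mix of clusters is argued against by the ratio stratified by cluster, 10.6 (5.29 to 21.4). Library 1 held Y-linked RNA and no Xist, while most sexed phagocytes of library 2 held Xist; phagocytes of library 2 with Y-linked RNA alone had Il10 at 4.29 CPM (0.885 to 12.5, 3 UMIs in 57 cells), against 0.807 (0.324 to 1.66) in library 1 and 11.5 in those with Xist alone. Of the 57 cells, 18 lay on the BC3 side of the tags, against 31 of the 790 with Xist alone. The contrast of sexes within library 2 is thus also partly one of tag sides. The few Il10 UMIs leave sex and the animals or preparation of each library open. With 2 libraries that differ in all of these, they cannot be told apart. Apart from sex, no biological explanation was tested.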
